A study of Drosophila melanogaster with 14 samples.

How the data were processed

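RNA was extracted from whole flies frozen at the end of the assay, pooled in equal amounts over 1, 2 or 3 experiments, labelled with biotin and hybridised to a 1-colour Affymetrix array, per the labels' protocols. The deposited values are intensity values that were normalized between arrays with RMA, per the submitters' processing notes. The software, version and settings of that step are not given in the sources used here, and detection calls and scanner files were not used here. The intensity values deposited by the authors are on a linear scale, as read from medians of 47.2 to 48.8 and a largest value of 14263; that the table was raised back from the log scale on which RMA works was not stated. RMA draws all arrays to 1 distribution, so a change in total RNA would not be seen, and it has no floor, so small intensities (the lowest was 2.94) hold little information on presence.

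The table held 14010 probe sets and 14 libraries, and no value column lacked a sample. The 44 spike-in control probe sets were left out and 13966 were tested, with no filter on low values. Log2 was taken before every fit. Gene names came from the platform annotation. Of the tested probe sets, 12443 had 1 gene symbol, 327 several and 1196 none listed; 12394 of the symbols were looked up by gene ID in the RefSeq gene table of the release 6 assembly and 49 were kept as annotated, giving 10844 genes. No coordinates were used except the order of genes in that table, since the files name no build. Where a gene had several probe sets, the one with the highest mean level stood for it.

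Libraries were grouped by their titles. The 8 control male and 4 knockdown male libraries entered the tests. Replicate numbers were given in order of deposit and pair nothing. The library with conflicting labels was kept out and tried as control and as knockdown. Before averaging, libraries were checked for duplicates: the SD of the log2 differences between the control libraries of a time was 0.31, 0.161, 0.24 and 0.213 at 0, 2, 5 and 8 h, and no pair of libraries was identical.

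Tests were run in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Knockdown was tested against control with no time term, since the series description called time not discriminative. Time was tested as a factor with a moderated F test and genotype as covariate. The change of the knockdown effect with time was tested as the interaction of genotype with hours, because there was 1 knockdown library per time. Fold differences are 2 to the power of the log2 difference, while means and SDs are of intensities. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Comparisons of 1 library with 1 have no test; the median difference of a list was ranked among 10000 random lists matched on mean level in 20 bins, drawn with replacement.

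The lists, the named genes and the main designs were fixed before the data were examined. There were 26 lists: P450 genes, the neighbours of Cyp6g1, resistance-linked P450 genes, glutathione S-transferases, UDP-glycosyltransferases, carboxylesterases, ABC transporters, small RNA pathway, immune peptides, Turandot, heat shock, circadian, carbohydrate digestion, nutrient response, ribosome, respiratory chain and driver or marker genes, with tissue lists for yolk and eggshell, ovary, accessory gland, testis, digestive proteases, photoreceptors, muscle, neurons and fat body. The accessory gland list was built on symbols and holds Acp65Aa, an adult cuticle protein gene. The immune peptide list holds PGRP-SB1, a peptidoglycan recognition protein gene. Yp1 is in both the yolk and the fat body list. Named genes for the knockdown were Cyp6g1, up to 12 of the largest increases and 12 of the largest decreases among called probe sets with 1 symbol and all 4 knockdown values outside the control range, up to 4 members of each list, Cyp6g2 and Cyp6t3. For time they were the 5 smallest p and up to 4 members of the circadian, carbohydrate digestion and nutrient response lists, and for the interaction the 3 smallest p. For single against pooled libraries they were the 5 largest differences each way, and for sex the 10 largest each way and up to 4 members of each reproductive list. Genes outside this rule are said to be chosen after their values were seen. Female transcripts were members of the yolk, eggshell and ovary lists at least 3 log2 units higher in the female library than in the median male.

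The scripts were tested on simulated data with 13966 probe sets. For knockdown against control, 66% of changes of 0.5 log2 units, 92% of 1 unit and 100% of 2 units were recovered, with 6 false calls among 185. For time the shares were 64%, 92% and 100%, with 6 false calls among 184. For the interaction they were 12%, 48% and 94%, with 6 false calls among 132. Noise was drawn independently for each probe set and library, with 50 changed probe sets of each size. Shifts shared by many probe sets of a library were not simulated. The shares may therefore be too high for the real data, and the false calls too few.

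Alternatives fixed before the data were examined were the library with conflicting labels as control or knockdown, time as a fixed or random term, averaged controls, no 0 h libraries, quantile normalization again, centring on medians, a filter on low values, an intensity trend, a 2-fold threshold, 1 probe set per gene, array weights, an unmoderated statistic with unequal variances, and each library left out in turn. For time they were also 3 times only, a linear trend and control libraries only. Leaving out both male libraries with the most female transcripts (knockdown male replicate 1 and control male replicate 5), and leaving out both single-experiment libraries of 0 h, were chosen after seeing the data. The former are called both libraries with female transcripts below.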

Results

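Gene expression was measured on 14 arrays in whole adult flies of Drosophila melanogaster aged 2 to 3 days, in which Cyp6g1 was targeted by RNA interference or left untargeted. Cyp6g1 encodes a cytochrome P450 enzyme whose raised expression has been linked to insecticide resistance. The knockdown flies carried a ubiquitously active Act5C-GAL4 driver and a transgene coding for a Cyp6g1 hairpin RNA under GAL4 control, and the control flies carried an actin GAL4 driver without the hairpin. Both genotypes were labelled as carrying the balancer chromosomes CyO and TM3. Flies were held on plates of sucrose agar treated with solvent and collected at 0, 2, 5 or 8 h. Each library held RNA of 1, 2 or 3 experiments, an experiment being a cohort of flies set up on its own day. The main comparisons used 8 control male and 4 knockdown male libraries, that is 2 control and 1 knockdown libraries at each time. A library of knockdown females at 0 h was described without a test. A further male library, pooled at 0 h, carried conflicting labels and entered no main comparison. Its title and genotype called it control, while the description of the series placed it as the pooled partner of a knockdown library. Median intensity per library lay between 47.2 and 48.8 over 13966 probe sets, and the number of arrays limited the precision of every comparison. The labels did not say whether both control libraries of a time came from separate flies, so p-values measure the spread between these libraries, which may be technical.

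Cyp6g1 was strongly reduced in every library labelled knockdown. It had an intensity of 604.5 ± 148 (SD, n = 8) in control males and 42.2 ± 9.43 (SD, n = 4) in knockdown males, a 14.2-fold difference that left 7.06% of the control level. Control males ranged from 361.1 to 815.8 and knockdown males from 32.5 to 55.0. The log2 difference was -3.83 (SE 0.19), with an adjusted p of 1.12e-07 in limma and an exact two-sided permutation p of 0.00202, which came from 495 arrangements of the libraries. The single female knockdown library had an intensity of 27.7. The library with conflicting labels had 27.9, below every control library, so it is called here the library labelled control with conflicting labels, and no direction was drawn from its label.

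**Figure D1:**
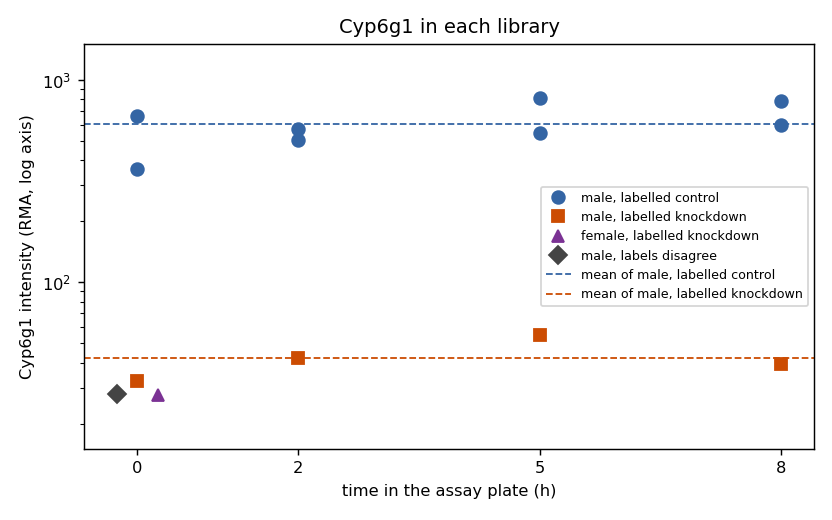
Intensity of Cyp6g1 (log axis) in each of the 14 libraries against time in the assay plate in hours; points are libraries and dashed lines are the means of the 8 control and the 4 knockdown male libraries. Control males lie between 361.1 and 815.8, knockdown males between 32.5 and 55.0, and the library with conflicting labels, drawn slightly left of 0 h, lies at 27.9.

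Beyond Cyp6g1, the knockdown males differed from the controls in a small set of genes led by a transporter. Mrp5, an ABC transporter of the multidrug resistance protein family, rose 5.06-fold, from 66.3 ± 9.57 (SD, n = 8) to 337.5 ± 69.3 (SD, n = 4), with a limma adjusted p of 1.41e-07. CG16826 was 3.47-fold lower, at 1252 ± 424 (SD, n = 4) against 4172 ± 780 (SD, n = 8). CG13947 was 3.22-fold lower on the brighter of its 2 probe sets, at 1103 ± 335 (SD, n = 4) against 3506 ± 984 (SD, n = 8). In all, 16 probe sets of 15 genes passed an adjusted p of 0.05, 6 of them higher and 10 lower in the knockdown. In each of the 16, the 4 knockdown values lay outside the range of the 8 controls. Over all probe sets such separation was seen in 93, or 0.666%, where chance gives 0.404%.

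The other genes changed by less than 2-fold. CG18549 rose 1.77-fold, the lysozyme gene LysP 1.58-fold from 200.6 ± 23.9 to 317.8 ± 38.3, the glutathione S-transferase gene GstE10 1.41-fold, CG3285 1.34-fold and CG12934 1.25-fold. Levels were 1.76-fold lower for Cyp6a17, 1.51-fold lower for CG1774, 1.49-fold lower for Cyp6a23, 1.45-fold lower for CG5273 and 1.29-fold lower for CHMP2B, a subunit of the ESCRT-III membrane remodelling complex. Ctr9, a subunit of the Paf1 transcription elongation complex, was 1.63-fold lower, with a log2 difference of -0.70 (SE 0.084). The adjusted p of these genes lay at or below 0.0341 in limma. Cyp6a17 and Cyp6a23 are adjacent measured genes and related in sequence, so that cross-hybridisation between them was not excluded. The count of 16 was 94 with time point as a fixed factor and 31 without the 0 h libraries. It was 9, 10 and 7 without knockdown male replicates 2, 3 and 4 in turn, and with the control libraries of each time averaged it was 6 without and 22 with time point as a block, 11 of the 16 being among the 22. Of 28 or 29 alternatives, CG1774 and CG12934 each lost the call in 16, Cyp6a17 in 12, CHMP2B in 11, CG3285 in 10, GstE10 and CG5273 in 9, LysP in 7 and CG18549 in 6, and the other 6 genes in 3 or fewer. Except where the controls were averaged, these counts, the 16 and the fixed-factor 94 among them, take both controls of a time as independent.

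**Figure D2:**
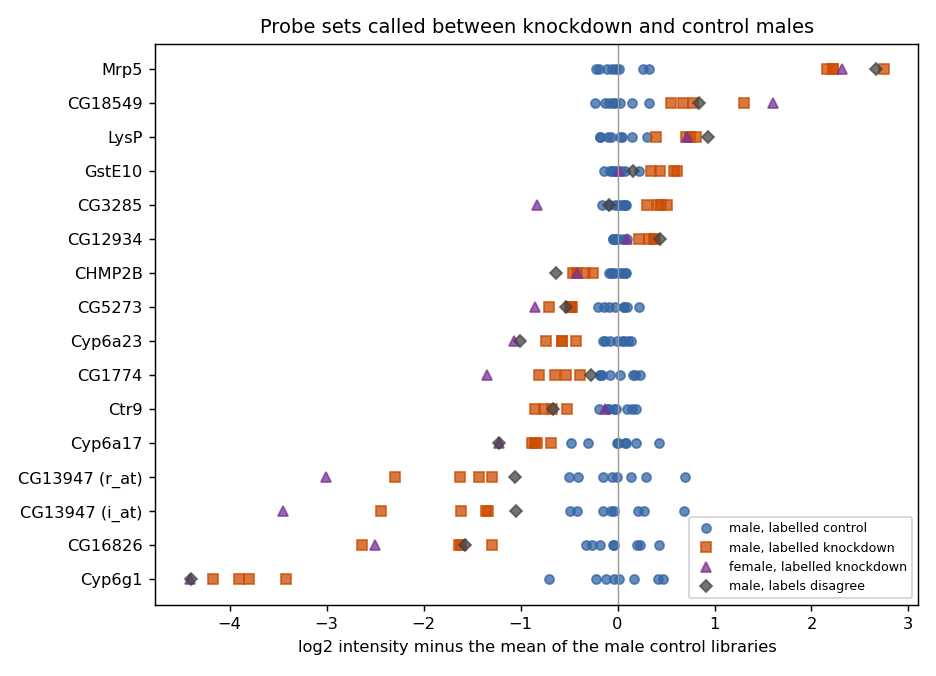
The 16 probe sets called between knockdown and control males, each with the log2 intensity of every library minus the mean of the 8 male control libraries on the horizontal axis; each point is a library and colours and shapes give the labels. All 4 knockdown males lie outside the control range for each probe set, and the library with conflicting labels lies nearer the knockdown mean for 13 of the 16.

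Genes of detoxification were examined as lists. Of 81 cytochrome P450 genes measured, 3 fell (Cyp6g1, Cyp6a17 and Cyp6a23), none rose and 78 did not pass the test; adjusted over the list alone 5 fell, the added genes being Cyp28d2 and Cyp6a13, chosen for naming after their values were seen. The genes beside Cyp6g1 on the chromosome did not pass, with log2 differences of -0.10 (SE 0.065) for Cyp6g2 and -0.20 (SE 0.087) for Cyp6t3. Of 11 P450 genes linked to insecticide resistance, 1 fell (Cyp6g1), and adjusted over the list alone 3 fell, with Cyp12a4 at 254.0 ± 37.4 (SD, n = 4) against 368.7 ± 84.0 (SD, n = 8) and Cyp4p1 at a log2 difference of -0.41 (SE 0.145). Of 36 glutathione S-transferase genes, 33 had a positive difference but 1 rose (GstE10); adjusted over the list alone 2 rose, GstT3 being the other. GstE6 stood at 259.4 ± 45.0 (SD, n = 4) against 188.8 ± 50.4 (SD, n = 8) without passing, though it passed under 4 of 29 alternatives. Without the 0 h libraries its limma adjusted p was 0.0142, at a log2 difference of 0.47. Of 10 ABC transporters, 1 rose (Mrp5); adjusted over the list alone 2 rose, with Mdr65 at a log2 difference of 0.64 (SE 0.149). None of 33 UDP-glycosyltransferase and none of 12 carboxylesterase genes passed; adjusted over the list alone Est-Q rose, at 63.5 ± 15.9 (SD, n = 4) against 43.6 ± 7.08 (SD, n = 8).

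Immune peptides and tissue markers had no member called over all probe sets. None of 12 antimicrobial or immune-induced peptide genes passed over all probe sets, and adjusted over the list alone 4 were lower in the knockdown. These were Mtk at 528.5 ± 229 (SD, n = 4) against 909.8 ± 221 (SD, n = 8), Drs, which encodes the antifungal peptide drosomycin, at 799.0 ± 308 against 1306 ± 360, DptB and Drsl5. The list median was -0.32 on the log2 scale, with a camera adjusted p of 0.000134, an adjusted p of 0.227 with an estimated correlation and a fry adjusted p of 0.0438. No member passed in the lists of small RNA pathway (10 measured), Turandot (2), heat shock (5), yolk and eggshell (19), ovary (15), accessory gland (17), testis (24), circadian (10), digestive protease (29), carbohydrate digestion (15), nutrient response (19), cytosolic ribosome (31), respiratory chain (64), photoreceptor (11), muscle (15), neuron (12), fat body (11) and driver or marker genes (2). Camera with its preset correlation called 12 of the 26 lists. The lists called higher were the transferases, UDP-glycosyltransferases, ABC transporters, yolk and eggshell, digestive proteases, carbohydrate digestion, ribosome and respiratory chain. Those called lower were the resistance P450 genes, the immune peptides, heat shock and testis. The resistance list holds Cyp6g1, the targeted gene, and had a mean of -0.51 and a median of -0.12. It was not tested without Cyp6g1, so its call is not evidence apart from the knockdown. With an estimated correlation camera called no list, so the camera calls rest on the preset value, and the lowest adjusted p of any list was then 0.227. Fry gave an adjusted p under 0.05 for ABC transporters (0.00444) and immune peptides (0.0438) only. The ABC transporter list holds Mrp5, itself a called gene, and had a mean of 0.35 and a median of 0.076. It was not tested without Mrp5. Median and mean differed in sign for the P450 (0.014 and -0.061), ovary (-0.0029 and 0.071), muscle (-0.052 and 0.039) and fat body lists (-0.044 and 0.063), none of them called. Without knockdown male replicate 1 and control male replicate 5, an alternative chosen after seeing the data, 11 lists were called, 8 of the 12 among them. With an estimated correlation none was called in this setting, the lowest camera adjusted p being 0.133. Yolk and eggshell genes were among the 8, at a camera adjusted p of 1.98e-05 with the preset correlation. Knockdown male replicate 3, which held some female transcripts, was kept. The 3 lists beyond these 8 were lower in the knockdown, with camera adjusted p of 0.0350 for P450 genes, 0.00436 for the neighbours of Cyp6g1 and 0.0211 for Turandot, or 0.575, 0.133 and 0.187 with an estimated correlation. The P450 list also holds Cyp6g1, and its median was then -0.0016. Those lost had adjusted p of 0.354 for digestive proteases, 0.551 for carbohydrate digestion, 0.110 for UDP-glycosyltransferases and 0.0594 for heat shock. The carbohydrate digestion median was then -0.018 against 0.16, and that of the proteases 0.091 against 0.18. Among lists still called, medians also shrank for testis (-0.14 against -0.29), yolk and eggshell (0.15 against 0.28), transferases (0.10 against 0.17) and immune peptides (-0.20 against -0.32). Those of respiratory chain (0.18 against 0.21) and ABC transporters (0.075 against 0.076) moved less, and that of ribosome genes rose (0.11 against 0.052).

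Transcripts typical of females and of the testis differed between the libraries. In knockdown male replicate 1, 21 yolk, eggshell and ovary transcripts stood at a median of 8.57% of their level in the female library, and in control male replicate 5 at 1.58%. The highest of these was Vm34Ca, a vitelline membrane gene, at 37.3% in knockdown male replicate 1, where the eggshell gene Cp15 was at -0.044% relative to the male median. In control male replicate 5, Cp15 stood at 9.16% and the germline gene vas at 10.2%. Knockdown male replicate 3 had a smaller rise, at a median of 0.631%, with Cp15 at 1.72%, Cp16 at 1.49% and Cp18 at 1.65%. This library was kept in the alternative given below. Testis genes had median shifts of -0.55 and -0.64 on the log2 scale in control and knockdown male replicates 1, the single-experiment libraries of 0 h. Without knockdown male replicate 1 and control male replicate 5, an alternative chosen after seeing the data, 16 probe sets were again called, 13 of them shared, and GstE10, CG3285 and CG1774 were no longer called. Their log2 differences moved little, to 0.46 from 0.49, 0.39 from 0.42 and -0.55 from -0.59, with adjusted p of 0.0831, 0.0939 and 0.0986 in limma over fewer libraries.

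**Figure D3:**
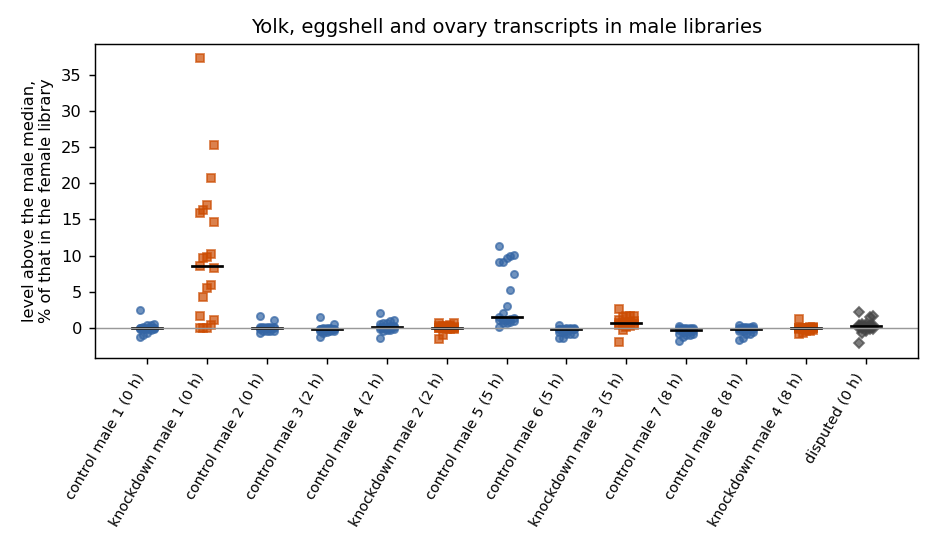
Level of 21 yolk, eggshell and ovary transcripts above the male median, in percent of that in the female library (vertical axis), in the 12 male libraries and the library with conflicting labels (marked disputed); points are transcripts and black lines are medians. The median is 8.57% in knockdown male replicate 1 and 1.58% in control male replicate 5.

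Time in the assay was the next question, since the series description reported no difference attributable to time. Members of the accessory gland and testis lists were among the genes that rose between 0 h and 8 h. CG17744 rose from a mean of 52.3 ± 8.77 (SD, n = 3) at 0 h to 105.0 ± 6.04 (SD, n = 3) at 8 h, and CG7634 from 63.2 to 110.5. The other genes with the smallest p were CG14995, CG42827 and CG16957, with log2 differences at 8 h of 0.73, 0.76 and 0.48 (SE 0.082, 0.091 and 0.070), and all 5 had a limma adjusted p of 0.0102. In total 835 probe sets changed over the 4 times with genotype as covariate, 645 with a higher and 190 with a lower level at 8 h than at 0 h, and 427 ran in one direction through 0, 2, 5 and 8 h. None of the 16 knockdown probe sets was among them. No probe set differed between 2 h and 0 h in limma, 1898 having an unadjusted p under 0.05, while 1078 were higher and 479 lower at 5 h, and 1069 higher and 378 lower at 8 h.

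By list, 9 of 17 accessory gland genes and 7 of 24 testis genes rose with time, and adjusted over the list alone 16 of each changed. The lists differed in how far this rested on the 0 h libraries. Without both single-experiment libraries of 0 h, an alternative chosen after seeing the data that left 1 library at 0 h, the testis median difference between 8 h and 0 h was 0.098 instead of 0.41, with 3 genes called, and that of accessory gland genes 0.83 instead of 0.63, with 11 called. Among the 2, 5 and 8 h libraries alone the medians of 8 h minus 2 h were 0.048 with no testis gene called and 0.47 with 4 accessory gland genes called. Examples, chosen after their values were seen, were the seminal protein gene Acp26Ab, from 246.7 to 540.4 ± 87.2 (SD, n = 3), and the sperm chromatin gene Mst77F, from 333.5 to 558.7 ± 98.6 (SD, n = 3). None of 10 circadian and none of 15 carbohydrate digestion genes passed (1 and 0 adjusted over the list alone). Among them tim stood at 96.9 at 0 h and 162.2 at 8 h and Mal-A4 at 574.8 and 235.1, with adjusted p of 0.102 and 0.117 in limma. Among the 2, 5 and 8 h libraries alone, 1 circadian gene was called, tim, with a log2 difference of 0.61 between 8 h and 2 h and a limma adjusted p of 0.0469. Without both single-experiment libraries of 0 h its difference between 8 h and 0 h was 0.19. Mal-A4 read 782.5 and 670.0 in the single-experiment libraries of 0 h and 272.1 in the pooled one. Without the former the median of carbohydrate digestion genes turned from -0.23 to 0.26, with 3 higher and 2 lower at 8 h, and that of digestive proteases from -0.23 to 0.29, with 2 higher and 3 lower. Among the 2, 5 and 8 h libraries these medians were 0.075 and -0.025, with 2 and 3 genes lower. Of 19 nutrient response genes, Sirt2 rose, from 69.9 to 92.3 ± 2.54 (SD, n = 3), and the lipase gene Lip4 changed, with means of 130.4, 76.1, 95.6 and 106.2 at 0, 2, 5 and 8 h. Among the other lists, 3 transferase genes, 2 digestive protease genes and 1 heat shock gene fell, 2 ribosome genes and 1 small RNA pathway gene rose, and 3 respiratory chain genes rose and 3 fell. P450 genes gave 3 higher and 1 lower and immune peptides 2 higher and 1 lower. Accessory gland and testis genes had their lowest shifts in 0 h libraries, accessory gland at -0.57 in control male replicate 2 and -0.52 in knockdown male replicate 1, and testis as given above. In neither list were all 0 h libraries low. Accessory gland genes stood at -0.014 in control male replicate 1, against -0.30 in control male replicate 3 of 2 h. Testis genes stood at 0.0025 in control male replicate 2. Without knockdown male replicate 1 and control male replicate 5, 1 of 17 accessory gland and 2 of 24 testis genes were called, on fewer libraries, while the median log2 differences between 8 h and 0 h were 0.56 against 0.63 and 0.35 against 0.41.

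The count of time-dependent probe sets moved with most single libraries. It was 410, 2076, 364, 388, 336, 262 and 210 without control male replicates 1, 2, 3, 4, 6, 7 and 8, and 179, 498, 267 and 230 without knockdown male replicates 1, 2, 3 and 4. It was 152 among the 2, 5 and 8 h libraries, all pools of 3 experiments, with 91 shared, and 0 among the 8 control libraries alone in limma, where 1610 probe sets had an unadjusted p under 0.05.

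**Figure D4:**
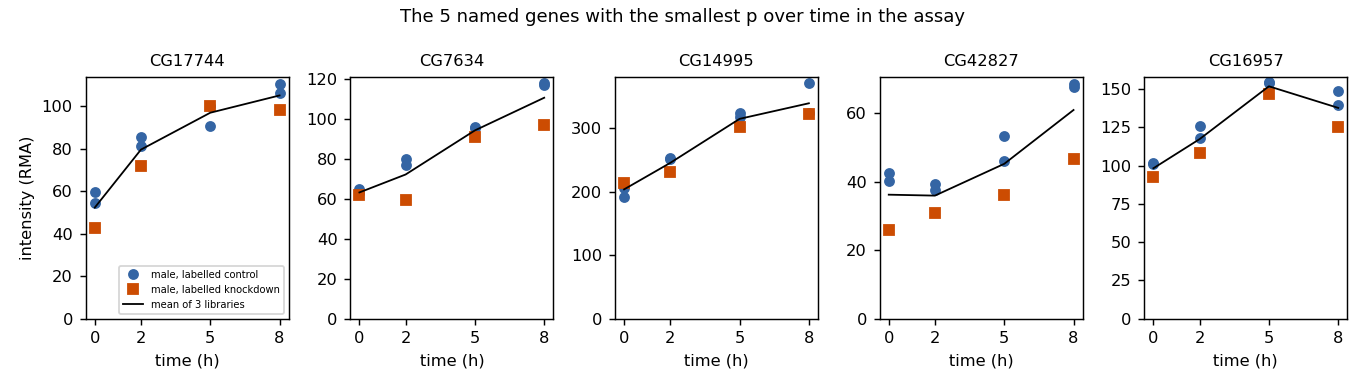
Intensity of CG17744, CG7634, CG14995, CG42827 and CG16957 (vertical axes, from 0) against time in the assay in hours; points are the 12 male libraries and lines join the means of the 3 libraries of each time. CG17744 goes from a mean of 52.3 at 0 h to 105.0 at 8 h.

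The knockdown effect was not found to change with time. No probe set passed in the limma interaction of genotype with hours; 720 had an unadjusted p under 0.05 and the smallest adjusted p was 0.916. The genes with the smallest p were CG1575, at -0.10 log2 units per hour (SE 0.020), the muscle actin gene Act79B, at 0.11 (SE 0.025), and BckdhA, at 0.082 (SE 0.019). In simulated data a knockdown effect reaching 1 log2 unit at 8 h was recovered for 48% of changed probe sets, so smaller changes would often be missed. The simulated noise was independent between probe sets, so recovery in the real data may be lower.

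Libraries of single and pooled experiments were compared at 0 h, with 1 library on each side and hence no test. The single-experiment control male library had 111 probe sets at least 2-fold higher and 35 at least 2-fold lower than the pooled one, and the SD of the log2 differences was 0.31. Carbohydrate digestion genes had a median difference of 1.21 and digestive proteases of 0.94, each above all of 10000 random lists matched on level. The 5 largest increases were CG8997, CG7953, CG7916, CG11911 and CG31872, CG8997 reading 1028 against 189.1. The 5 largest decreases were CG17298, CG8483, CG8736, Sclp and the chitinase gene Cht5, CG17298 reading 156.7 against 963.2. Testis genes had a median difference of -0.46, below all of the random lists. The single-experiment knockdown male library had 213 probe sets higher and 189 lower than the library with conflicting labels, with an SD of 0.41. The largest increases were Vm34Ca, the maternal thioredoxin gene dhd, the yolk protein genes Yp2 and Yp1 and the germline gene osk, with Vm34Ca at 5371 against 80.6. The single-experiment library here is knockdown male replicate 1, which carried the female transcripts described above. These increases were therefore not taken as an effect of pooling. The largest decreases were Nckx30C, nAChRbeta1, djl, CG7069 and CG10077, with Nckx30C at 28.4 against 174.5.

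Female and male knockdown flies at 0 h were compared again with 1 library on each side, and genes of the reproductive lists were among the largest differences. In the female library 1328 probe sets were at least 2-fold higher and 1161 at least 2-fold lower than in the male, and 202 and 482 at least 4-fold. All 19 yolk and eggshell genes were at least 2-fold higher, with a median log2 difference of 2.59, and 9 of 15 ovary genes were. The eggshell genes Cp15 (7558 against 72.8), Cp38 (7272 against 84.8), Cp16 and Cp36 were among the highest, as was the mucin gene Muc12Ea at 1776 against 11.1. The remaining genes among the 10 largest increases were CG13114, Cp19, yellow-g, yellow-g2 and CG4009. Of 17 accessory gland genes 16 were at least 2-fold lower in the female, with a median of -5.18, and of 24 testis genes 14 were, with a median of -3.11. The ejaculatory bulb gene Ebp read 7.21 against 2390 and the seminal protein gene Acp53C14a 10.1 against 1833. EbpII, Mst57Da, Acp95EF, CG34168, the testis tubulin gene betaTub85D, CG12699, CG17377 and Anp completed the 10 largest decreases. Small RNA pathway genes had a median of 0.94, above 99.96% of random lists. The male partner was knockdown male replicate 1, which carried the female transcripts described above; against the mean of the 4 knockdown males, 909 probe sets differed by at least 4-fold, against 684. Against the mean of the other 3 knockdown males, of later times and chosen after seeing the data, the median of yolk and eggshell genes was 4.69 instead of 2.59, and that of accessory gland and testis genes -5.63 and -4.13.

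The library labelled control with conflicting labels was set beside both groups. Mrp5 read 416.2 in it, against 56.4 to 82.5 in the 8 control males. Cyp6a17 read 26.9 and CHMP2B 56.2, both below every control male. GstE10, at 88.8, and CG3285, at 131.2, lay within the control range. With this library counted as control, no probe set passed in limma, 1268 having an unadjusted p under 0.05, and the adjusted p of Cyp6g1 was 0.183. With it counted as knockdown, 13 probe sets passed, all of them among the 16.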

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

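Tests in this part other than the counts of splits and the ranking of neighbouring genes were chosen after the result was seen; the 81 splits within time points were added once the drawn splits were known, with their bound set before they were run.

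Several results stood apart from their group. Among knockdown males, replicate 1 was apart from the others in Mrp5, at 441.1 against 294.4 to 307.5, and in CG5273, at 69.4 against 80.6 to 81.8. Among control males, replicate 1 was apart in the median shifts of glutathione S-transferases (0.19 against -0.11 to 0.0061), testis genes (-0.55 against -0.013 to 0.15) and carbohydrate digestion genes (0.72 against -0.42 to 0.10). Control male replicate 5 was apart in yolk and eggshell genes (0.60 against -0.17 to 0.013), and control male replicate 7 in neuron genes (-0.19 against -0.0075 to 0.066). These were 7 of 82 sets of values examined, where chance sets apart about 5%, and lists measured in the same libraries are not independent. Outside the tested groups, Mrp5 read 416.2 in the library with conflicting labels and 328.1 in the female knockdown library, against 56.4 to 82.5 in control males. There was no female control library, so the female value does not separate sex from knockdown. Not every called gene was knockdown-like in the female library: Ctr9 read 145.2 there, within the 139 to 181.9 of control males.

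The library labelled control with conflicting labels had knockdown-like values. A wrong genotype label on this library was tested by its position: 13 of the 16 called probe sets lay nearer the knockdown mean than the control mean, whereas with each control male left out of the calls in turn this held for 4 of 19 in replicate 1, 1 of 15 in replicate 5 and 0 in the other control males. A swap with a library labelled knockdown would need a partner with control-like Cyp6g1, and 0 of the 5 libraries labelled knockdown had one. A wrong label is therefore a candidate explanation, in line with the description of the series, while an exchange with a library outside the series stays open. No biological explanation was tested, since the design gives none.

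The 16 probe sets called between knockdown and control males were set against other splits of the 12 libraries. Of 100 splits, 2 gave as many, the real one included. This share was under the bound of 0.05, but these splits took no account of time point. The highest other split gave 40, with knockdown male replicate 1 and control male replicates 2, 3 and 4 on one side. Among all 81 splits that keep 1 library of each time in the set of 4, only 1, the real one, gave as many. The highest other of these gave 1, both without a time term and with time point as a fixed factor (94 in the real split). Of the 81, only the real split leaves both controls of every time on the same side. If those controls share RNA, which the labels do not settle, these counts cannot exclude chance. RNA of female flies in 2 male libraries is argued against as the whole cause, since the median ratio of the 16 differences without and with those libraries was 0.932, all keeping their sign. This is a weak test. The 16 were called with both libraries in and were apart from the controls in all 4 knockdown males, which makes a low ratio unlikely. Linked chromosome background around the called genes could not be settled: genes within 5 places of the 14 called genes other than Cyp6g1 had a median absolute statistic at the 93.2 percentile of 10000 random sets. These neighbours include LysB, LysC, LysD and LysE beside LysP, whose probe sets may read overlapping transcripts. The percentile was not computed without them. An effect of reduced Cyp6g1, an effect of the hairpin on other transcripts and the insertion chromosome stay open as untested, because 1 knockdown genotype was used.

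The 835 probe sets that changed with time exceeded other splits: 1 of 100 splits of the 12 libraries into 4 sets of 3, the real one, gave as many, and the highest other gave 132. The real sets keep both controls of each time together, here and among the 2, 5 and 8 h libraries below. RNA shared by those controls would also raise the real counts, and the splits cannot exclude this. Without knockdown male replicate 1 and control male replicate 5, which held female transcripts, the differences between 8 h and 0 h had a median ratio of 0.949 to the main ones. The count of calls dropped to 170 with fewer libraries. The ratio argues against female RNA in knockdown male replicate 1, a 0 h library, as the whole cause. It says little on control male replicate 5, a 5 h library. The probe sets were those called with both libraries in, so this too is a weak test. Fewer experiments in the 0 h libraries cannot account for differences among the 2, 5 and 8 h libraries, all pools of 3 experiments. There 152 were called, 91 of them shared, and 1 of 100 splits of the 9 libraries gave as many, against 66 in the highest other. The difference of these 91 from 0 h was not settled by this. Lip4, called in both fits, went from 130.4 at 0 h to 76.1 at 2 h, while its 8 h minus 2 h log2 difference was 0.48. For the other 744 calls the number of experiments cannot be told apart from time, because every 0 h library pooled fewer experiments than the later ones. An effect of hours on the plate, of feeding or of time of day stays open as untested.

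For the knockdown effect changing with time, 48 of 100 splits gave at least the real count of 720 probe sets at an unadjusted p under 0.05, and the highest other gave 3517, so chance was not excluded.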

How the results depend on the processing

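Leaving out both libraries with female transcripts, or both single-experiment libraries of 0 h, and the mean of 3 knockdown males in the female comparison (999 probe sets at 4-fold, against 684) were chosen after seeing the data; the other settings were planned. The Cyp6g1 difference stayed between -3.96 and -3.34 under 29 alternatives and lost its call under 1, the library with conflicting labels as control (-3.34, adjusted p 0.183). The count of 16 knockdown probe sets became 0 with that library as control, 94 with time as a fixed factor, 6 with averaged controls, 31 without the 0 h libraries, 5 with a 2-fold threshold as well, 46 with array weights, 1 with the unmoderated statistic and 28 without both single-experiment libraries; without 1 library at a time it ranged from 7 to 19. The count of 835 time probe sets became 152 at 2, 5 and 8 h only, 1484 with a linear trend, 0 in control libraries only, 371 with the library with conflicting labels as knockdown, 170 without both libraries with female transcripts and 479 without both single-experiment libraries; without 1 library it ranged from 179 to 2076. Fewer libraries lower the power in several of these settings; otherwise the cause was not tested. The interaction gave 0 calls under all 18 alternatives, with 297 to 1366 probe sets at an unadjusted p under 0.05. List calls went from 12 to 0 with an estimated correlation. By replicate number, no paired analysis was possible because these numbers follow the order of deposit. Time points do pair the groups: with time point as a random block 20 probe sets were called, all 16 among them, and with the controls of each time averaged and time point as a block 22 were (4 higher, 18 lower), 11 of the 16 among them.

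Signs turned in genes that were not called. Without the 0 h libraries the differences were 0.0052 for Hsp68, 0.014 for DnaJ-1, -0.042 for Yp2, -0.27 for osk, -0.078 for CycB, -0.073 for otu and -0.10 for RpS5b. Without knockdown male replicate 1 they were -0.15 for osk, -0.038 for CycB, -0.062 for otu and -0.033 for RpS5b, and without any other single library at most 1.08, 0.51, 0.26 and 0.62. Without both single-experiment libraries they were -0.21, -0.059, -0.087 and -0.045 for these 4 genes. DnaJ-1 stood at 0.0017 with array weights and Mst57Dc at 0.0062 without both libraries with female transcripts. Of 433 values of the 15 named called genes under alternatives, 322 kept the call, 111 lost it and 0 turned the sign. Of 2619 values of the 91 named genes not called, 12 became called and 17 turned the sign. The cause was not tested. Detection calls were not used here, so how far dim probe sets lay above background is unknown; 14 of the 16 were called among probe sets above the median level.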

Other observations

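All genes in this part were chosen after their values were seen.

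Lysozyme genes next to LysP ran against it. LysP was higher in the knockdown males, while its neighbours LysB, LysD and LysE had log2 differences of -0.99 (SE 0.233), -1.08 (SE 0.246) and -1.04 (SE 0.220) and LysC of -0.91 (SE 0.295). Mean intensities were 2187 ± 876 (SD, n = 4) against 4279 ± 1311 (SD, n = 8) for LysB and 804.6 ± 277 (SD, n = 4) against 1649 ± 508 (SD, n = 8) for LysE. None of these 4 passed in limma over the 12 libraries, with adjusted p between 0.187 and 0.468. All 4 passed without the 0 h libraries, where 31 probe sets passed in all, with adjusted p from 0.0104 for LysE to 0.0488 for LysC, and none passed without both libraries with female transcripts, with adjusted p of 0.0808, 0.571, 0.0808 and 0.0709 for LysB, LysC, LysD and LysE. Their log2 differences were then larger, at -1.23, -1.20, -1.33 and -1.25. The genes are close in sequence, so their probe sets may read overlapping transcripts and were not taken as separate evidence.

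The largest decreases with time at 8 h, among called probe sets, were CG5550, from 99.6 ± 55.3 (SD, n = 3) to 17.1 ± 1.31 (SD, n = 3), and CG17298, from 540.5 ± 405 (SD, n = 3) to 98.4 ± 10.4 (SD, n = 3). The 0 h mean of CG17298 was 329.1 without control male replicate 2, which read 963.2, and that of CG5550 was 128.1 without this library, which read 42.7. LManVI, LManIII and LManV, which encode lysosomal alpha-mannosidases, had log2 differences of -1.84 (SE 0.342), -1.56 (SE 0.305) and -1.38 (SE 0.294). That of the serine protease gene Jon25Bii was -1.33 (SE 0.315). In these genes the single-experiment libraries of 0 h (control and knockdown male replicates 1) read above the pooled control male replicate 2. LManVI read 521.44 and 517.58 against 167.06, and LManIII 78.07 and 42.9 against 25.72. LManV read 630.91 and 623.64 against 250.1, and Jon25Bii 934.55 and 820.87 against 370.77. Their 8 h means were 100.38, 15.04, 179.17 and 273.95 in that order, so part of each fall lay between single and pooled libraries of 0 h. Among members of the immune peptide list Drs rose from 841.5 to 1465 ± 429 (SD, n = 3) and BomS2 from 413.2 to 648.5 ± 69.7 (SD, n = 3). PGRP-SB1, a peptidoglycan recognition protein gene in that list, fell from 235.2 to 129.9 ± 7.40 (SD, n = 3).

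The female transcripts of knockdown male replicate 1 and control male replicate 5 were not in the same proportions. In the former, vitelline membrane genes were high (Vm34Ca at 37.3%, Vm32E at 20.8% and Vm26Aa at 17.1% of the female level) and the late eggshell genes Cp15, Cp16 and Cp18 were at -0.04%, 0.03% and -0.02%. In the latter, Cp15 and Cp18 stood at 9.16% and 5.22%, the germline genes bcd, otu, vas, CycB and osk between 7.49% and 10.2%, and Vm34Ca at 1.13%. Knockdown male replicate 1 had the highest level of the male libraries for 14 of the 21 transcripts and control male replicate 5 for 7. Knockdown male replicate 3 was raised less, with Cp15 at 1.72%, Cp18 at 1.65% and Vm34Ca at 0.5%.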
